A study of Mus musculus with 14 samples.

How the data were processed

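Total RNA of mouse cell cultures was extracted with Trizol, labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. The deposited table held 14 arrays with 45101 probe sets each, and its values were linear intensity values that the authors had already summarised from probes to probe sets. They ranged from 0.596 to 25702. How the authors corrected background, scaled the arrays and summarised the probes is not given in the sources used here, so the scale of the values stays unknown beyond what the values show. No genome build was given in the sources used here, and no coordinates are printed.

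The array medians differed by 0.374 on the log2 scale, which was under the limit of 0.5 set for further centring, and the values were used as deposited. Values below an intensity of 32 were raised to 32 before taking log2. A fold change of a gene that lies under this floor in 1 group is therefore understated. Of the probe sets, 34958 were assigned to a single gene symbol, 932 to several and 9211 to none in the platform annotation. Symbols were checked through Entrez identifiers against a RefSeq gene table of assembly GRCm38.p6, where 34754 matched and 0 changed. Of the 18194 genes represented, 9012 had several probe sets. The probe set with the highest mean over the 14 arrays stood for the gene. Probe sets of a gene opposed each other in direction for 115 of the 7273 genes with a called probe set in WT EB versus WT ESC, and for 75 of 6193 in TKO EB versus TKO ESC. A gene was tested where its probe set lay above the array's 40th percentile on at least 3 arrays, which left 14365 genes.

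Groups were taken from the sample titles. A model with 1 mean per group was fitted over all 14 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with trend), and p-values were adjusted by Benjamini-Hochberg within each of 5 comparisons, with a threshold of 0.05. The comparisons were WT EB versus WT ESC, TKO EB versus TKO ESC, the difference between these changes (the interaction), TKO ESC versus WT ESC and TKO EB versus WT EB. Every adjusted p of a single gene comes from limma. Errors of log2 fold changes are standard errors from this fit. The arrays of a group came from different cell lines, which the series text calls biological replicates. The spread between lines was estimated for each gene over all groups together. Errors and p-values of a comparison therefore also reflect the spread in groups outside it. For Pou5f1, for example, intensity ran from 32.8 to 55.2 in WT EB but from 17.1 to 7410.3 in TKO EB, which widens its error also in WT EB versus WT ESC. The number of arrays limits the precision.

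Gene lists were written down before the data were examined, 32 in all, covering cell cycle genes, pathways and markers of cell types that such cultures can hold. Of these, 30 with at least 5 tested members were tested with limma's camera against all other genes, two-sided, with a preset correlation between genes of 0.01 and adjustment over the lists of a comparison. The Rb family and a sex-linked list with fewer members were only described. The camera test was repeated with an estimated correlation between genes, which ended each of the 47 calls. The lowest adjusted p among them was then 0.241. Members past the threshold were counted over all genes and also adjusted over the list alone. Means of a list per array were compared by exact permutation of arrays, two-sided, which cannot go below p = 0.1 for 3 arrays against 3 and 0.0179 for 5 against 3.

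The named genes followed a rule fixed at the same time. In each comparison these were the 8 largest rises and the 8 largest falls among genes past the threshold, without overlap between the arrays of both groups except for the interaction, leaving out clone names and sex-linked genes, then up to 4 members of each list with the smallest adjusted p, and always Rb1, Rbl1 and Rbl2. Intensities of single arrays are given for some of them.

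The procedure was tested on simulated data in which 200 of 14365 genes were changed. For TKO EB versus WT EB it recovered 34.3% of genes changed by 1 on the log2 scale, 76.1% of those changed by 2 and 93.9% of those changed by 3. For TKO ESC versus WT ESC these shares were 25.4%, 74.6% and 90.9%, and for the interaction 7.5%, 53.7% and 80.3%. For WT EB versus WT ESC they were 28.4%, 71.6% and 92.4%, and for TKO EB versus TKO ESC 35.8%, 77.6% and 92.4%. The simulated noise was independent between genes and equally wide in every group. Among the real arrays the median SD of a gene was 0.416 in TKO EB and 0.194 to 0.281 in the other groups. The shares therefore hold for the simulated setting and not for the real comparisons with TKO EB.

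Lines B21, J1 and R1 were measured as ESC and as EB, as were the TKO lines 7-4-1, Dutch and Ta1-12, so the line names pair these arrays. Deviations from the group mean correlated between the ESC and EB arrays of the same line at -0.046 (B21), -0.078 (J1) and -0.037 (R1) in WT cells and at 0.066 (7-4-1), 0.196 (Dutch) and 0.09 (Ta1-12) in TKO cells. The consensus correlation within lines was 0.032. A fit with the line as a fixed block, on the lines with both stages, was an alternative.

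Further alternatives were quantile normalization, no filter or a stricter filter on dim probe sets, other rules for choosing probe sets, a variance prior without trend, array weights, other floors, a random block for the line, a minimum fold of 2, fits of only the groups compared, fits with only the TKO lines measured at both stages, and leaving out each array in turn. For the lists fry was used as well, which tests a list against no change while camera compares it with other genes, and for the correlation of genotype effects the TKO EB lines without ESC array. After the data were seen, fits without line Ta1-12, without the TKO EB arrays of Dutch and 14-14-4, with the pluripotency mean as a covariate and without genes of chromosomes 1, 8, 11, 12 and 19 were added. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.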

Results

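Gene expression was measured with microarrays in mouse embryonic stem cells (ESC), undifferentiated cells that can form the tissues of the embryo, and in embryoid bodies (EB), aggregates in which such cells differentiate. The cells were labelled wild type (WT) or TKO. The labels do not spell out TKO. It was read here as triple knockout of Rb1, Rbl1 and Rbl2, from the series title, which names the Rb gene family, and from common usage. These genes encode pocket proteins that hold back E2F transcription factors and entry into S phase. The series concerns whether cells without this family can leave the cell cycle and differentiate. There were 3 arrays of WT ESC and 3 of WT EB (lines B21, J1 and R1 at both stages), 3 of TKO ESC (lines 7-4-1, Dutch and Ta1-12) and 5 of TKO EB (the same lines with 2-55-2 and 14-14-4). The time of EB culture is not given in the sources used here.

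The median intensity was 86.1, 88.8 and 89.3 for WT ESC B21, J1 and R1, and 83.2, 89.2 and 86.6 for TKO ESC 7-4-1, Dutch and Ta1-12. It was 107.9, 105.5 and 92 for WT EB B21, J1 and R1, and 95.4, 87.2, 100.4, 89.4 and 100.5 for TKO EB 2-55-2, 14-14-4, 7-4-1, Dutch and Ta1-12. The first principal component held 67.5% of the variance and separated ESC (61.6 to 95.1) from EB (-109 to 25). WT EB lay between -109 and -81.1, TKO EB Ta1-12 at -98.6, 7-4-1 at -67.2, 2-55-2 at -61.4, 14-14-4 at -23.7 and Dutch at 25. Correlations across genes between arrays of a group were 0.953 to 0.987 in WT ESC, 0.977 to 0.985 in TKO ESC, 0.931 to 0.955 in WT EB and 0.836 to 0.953 in TKO EB. WT ESC B21 had a higher mean correlation with TKO ESC (0.98) than with the other WT ESC (0.96). The reverse held for WT ESC J1 (0.975 and 0.978) and R1 (0.96 and 0.97).

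Of the targeted genes, Rbl1 differed most between lines. Its signal was 693.8, 461.6 and 355.6 in WT ESC (B21, J1, R1) and 586.3 and 1089.6 in WT EB B21 and J1, with WT EB R1 between the WT ESC values. In TKO lines it was near or under the floor in 7-4-1 (24.5 in ESC, 38.3 in EB), 2-55-2 (31.7) and 14-14-4 (15.9). In line Dutch it was 250.3 in ESC and 377.1 in EB. In the arrays labelled TKO Ta1-12 it was 492.5 in ESC and 1095.9 in EB, within or just above the WT values. A second Rbl1 probe set gave 36.6 in ESC and 28.1 in EB of line 7-4-1, 88.2 and 135.5 in Dutch, and 328.2 and 194.2 in Ta1-12, with 296.7 to 413 in WT ESC and 114 to 174.2 in WT EB. Rb1 overlapped between genotypes (138 to 1018.4 in WT, 115.9 to 912.8 in TKO). Rbl2 in EB was 1726.9, 1683.7 and 722.8 in WT B21, J1 and R1, and 313.8, 296.8, 733, 456.1 and 1098.7 in TKO 14-14-4, 2-55-2, 7-4-1, Dutch and Ta1-12. A second Rbl2 probe set gave 392.5, 440.9 and 255.1 in the same WT EB and 94.3, 115.8, 169.7, 102.7 and 253.2 in the same TKO EB. In ESC it gave 122.5 to 175.6 in WT and 171.1 to 229.1 in TKO.

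By limma, Rbl1 had a log2 fold change of -2.63 ± 1.17 (adjusted p = 0.345) in TKO EB against WT EB (n = 5 and 3) and of -1.62 ± 1.31 (adjusted p = 1) in TKO ESC against WT ESC (n = 3 and 3). Rbl2 had -1.33 ± 0.42 (adjusted p = 0.303) in EB and 0.51 ± 0.47 (adjusted p = 1) in ESC, and Rb1 had -0.06 ± 0.65 (adjusted p = 0.973) and -0.78 ± 0.72 (adjusted p = 1). The position of the probes relative to the deleted parts of these genes is not given in the sources used here, and a probe outside the deleted part checks nothing. Directions drawn from the TKO group below include the arrays labelled TKO Ta1-12.

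**Figure D1:**
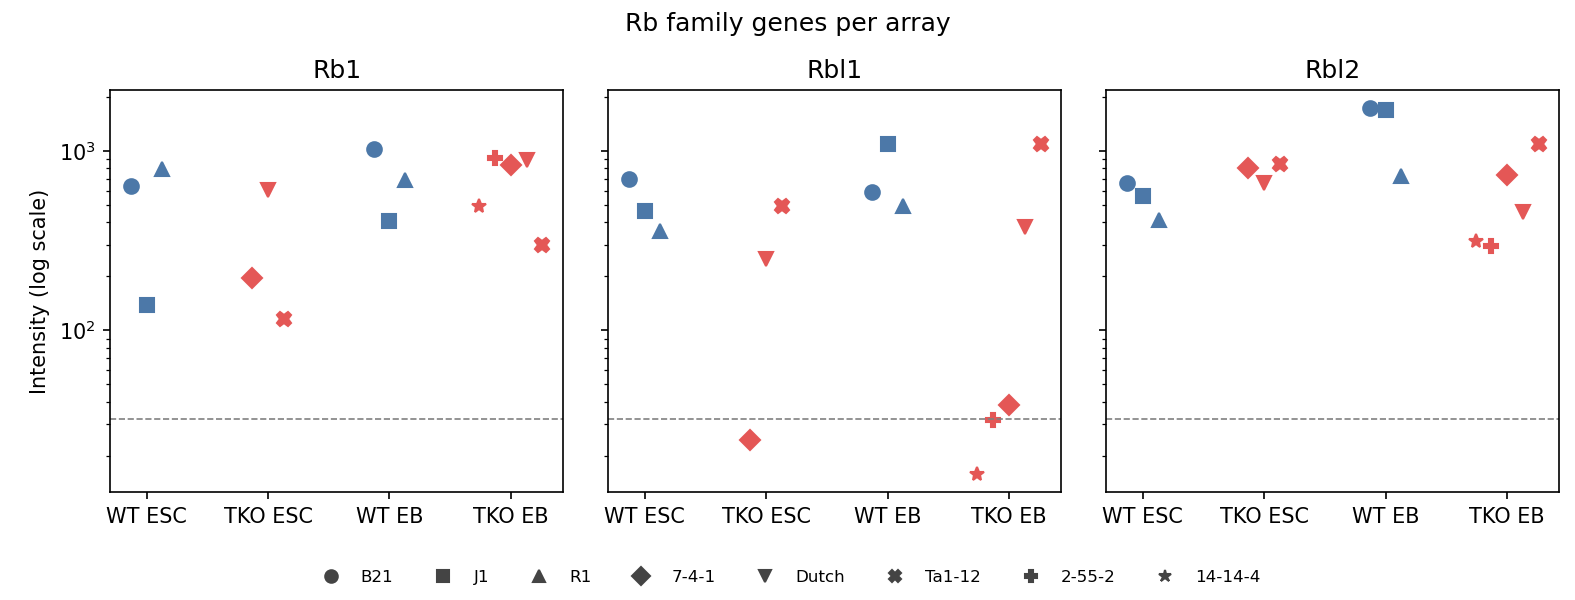
Intensity (log axis) of Rb1, Rbl1 and Rbl2 on each array, by group, with a marker shape per line and a dashed line at the floor of 32. Rbl1 lies between 15.9 and 38.3 in lines 14-14-4, 2-55-2 and 7-4-1, at 250.3 and 377.1 in Dutch, and at 492.5 and 1095.9 in Ta1-12.

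On differentiation of WT cells, genes of pluripotency fell and genes of mesenchyme, endoderm and cardiac muscle rose. Pou5f1 and Nanog, core transcription factors of pluripotent cells, fell in WT EB against WT ESC (n = 3 and 3), with log2 fold changes of -8.03 ± 1.58 (adjusted p = 0.00206) and -7.44 ± 1.51 (adjusted p = 0.00243). The pluripotency markers Utf1 (-7.07 ± 1.38) and Zfp42 (-7.00 ± 1.52), the nuclear receptor Esrrb (-6.95 ± 1.44), the germline gene Morc1 (-6.70 ± 1.39), Dnmt3l, a cofactor of DNA methylation (-6.57 ± 1.29), and the Nodal co-receptor Tdgf1 (-6.29 ± 1.67) fell as well. The matrix genes Dcn, Col3a1 and Lum rose by 8.56 ± 0.73, 8.45 ± 0.41 and 8.44 ± 0.54, the cadherin Cdh11 by 8.08 ± 0.45, the plasma proteins Afp and Ttr, made by visceral endoderm, by 8.53 ± 0.70 and 8.15 ± 0.53, the keratin Krt15 by 8.20 ± 1.71 and lysozyme Lyz1 by 8.45 ± 1.41.

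Among the lists in WT EB versus WT ESC, 23 of 27 pluripotency genes fell (24 adjusted over the list alone), with a mean change of -4.33 (camera adjusted p = 9.40e-10). Sox2 (-1.90 ± 0.30), Tet1, which oxidises methylcytosine (-3.26 ± 0.61), and the nuclear receptor Nr0b1 (-5.66 ± 1.09) were among them. All 10 primitive ectoderm genes fell (10 adjusted over the list alone, mean -3.56, adjusted p = 1.61e-05), among them Nodal (-5.92 ± 1.17) and its antagonist Lefty2 (-6.03 ± 1.32). Of 14 germline genes 8 fell (10 adjusted over the list alone, mean -2.61, adjusted p = 6.62e-05), including Ddx4 (-4.66 ± 1.01) and Mael, a factor of transposon silencing (-5.62 ± 1.22). With an estimated correlation the adjusted p was 0.536, 0.536 and 0.551 for these lists.

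Cell cycle genes moved down in WT EB. Of 39 E2F targets of G1/S and DNA replication 24 fell (26 adjusted over the list alone), with a mean of -1.21 (adjusted p = 1.45e-09; adjusted p = 0.551 with an estimated correlation). Mybl2, a transcription factor of cycling cells (-4.27 ± 0.82), the origin recognition subunit Orc1 (-3.04 ± 0.50) and the mismatch repair gene Msh6 (-1.97 ± 0.38) fell. Of 34 G2/M genes 21 fell (23 adjusted over the list alone, mean -1.20, adjusted p = 1.51e-07; adjusted p = 0.553 with an estimated correlation), including the spindle checkpoint kinase Bub1b (-1.72 ± 0.44) and the mitotic kinase Nek2 (-1.98 ± 0.54). All 7 CDK inhibitors rose (7 adjusted over the list alone, mean 2.43, adjusted p = 0.00123; adjusted p = 0.536 with an estimated correlation), with Cdkn1a at 2.02 ± 0.24, Cdkn2c at 3.51 ± 0.61, Cdkn2b at 3.47 ± 0.57 and Cdkn1c at 3.08 ± 0.63. The D cyclins Ccnd2 and Ccnd3 rose by 5.61 ± 0.69 and 0.96 ± 0.18, 2 of 6 members of the list of D cyclins and CDKs (3 adjusted over the list alone, mean 1.45, adjusted p = 0.116). In the E2F family of 10 genes, the repressor E2f4 (-1.03 ± 0.19) and the partner Tfdp2 (-0.69 ± 0.23) fell and E2f6 rose by 0.88 ± 0.24. The same 1 rise and 2 falls were counted when adjusted over the list alone (list mean -0.28, adjusted p = 0.261).

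Tissue genes rose in WT EB. Of 16 fibroblast genes 14 rose (14 adjusted over the list alone, mean 5.09, adjusted p = 1.62e-09), with Postn at 8.04 ± 0.38 and Col1a1 at 7.03 ± 0.54. Of 20 genes of definitive and visceral endoderm 18 rose (18 adjusted over the list alone, mean 4.04, adjusted p = 4.94e-06), among them the transcription factors Foxa1 (6.39 ± 0.80) and Gata6 (5.96 ± 0.82). Of 26 cardiac muscle genes 18 rose (20 adjusted over the list alone, mean 3.41, adjusted p = 7.96e-06), including Hand2, a heart transcription factor (5.42 ± 0.50), and cardiac troponin T, Tnnt2 (7.02 ± 1.17). Of 10 parietal endoderm genes 9 rose (9 adjusted over the list alone, mean 3.20, adjusted p = 1.39e-04), such as the basement membrane collagens Col4a1 (3.85 ± 0.52) and Col4a2 (4.19 ± 0.52). For these lists the adjusted p was 0.536 with an estimated correlation. Neural progenitor genes divided, with 5 of 17 rising and 2 falling (5 and 2 adjusted over the list alone, mean 1.03, adjusted p = 0.522), and Zic1 and Fabp7 rose by 5.22 ± 0.86 and 5.78 ± 1.33.

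In all, 6260 of 14365 genes (43.6%) passed the threshold in WT EB versus WT ESC, 3767 higher and 2493 lower, and 4225 of them changed at least 2-fold. The arrays of both stages did not overlap for 8653 of the 14365 genes tested, where chance gives 10% of genes for 3 arrays against 3. The median change of all genes was 0.13 as deposited and -0.07 after quantile normalization, under which 3025 genes were higher and 3478 lower. Relative to the median of all genes, the mean changed by -1.34 for E2F targets, -1.33 for G2/M genes, -4.46 for pluripotency genes, 3.28 for cardiac genes and 4.96 for fibroblast genes. With the line as a block, 119 of 124 named genes kept their call.

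TKO cells also gained tissue genes and lost pluripotency genes on differentiation. In TKO EB against TKO ESC (n = 5 and 3) the collagen gene Col3a1 rose by 8.68 ± 0.36, the imprinted Notch ligand homologue Dlk1 by 8.29 ± 0.36, Dcn by 7.87 ± 0.65, Postn by 7.79 ± 0.34, Cdh11 by 7.69 ± 0.40, Lum by 7.62 ± 0.48, the growth factor Ptn by 7.61 ± 0.55 and Igfbp5, which binds insulin-like growth factors, by 7.59 ± 0.60. The largest falls were in Morc1 (-4.62 ± 1.24), Nr0b1 (-4.23 ± 0.98), Eras, a Ras gene of ESC (-4.16 ± 1.08), Rasgrp2 (-4.16 ± 0.44), Dnmt3l (-4.13 ± 1.15), the homeobox gene Gbx2 (-4.12 ± 0.38), Esrrb (-4.11 ± 1.29) and Utf1 (-4.06 ± 1.24). With the line as a block, on 6 arrays, the 8 largest rises and Gbx2 kept their call and the other 7 falls lost it.

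Of the pluripotency genes, 16 of 27 fell in TKO EB (22 adjusted over the list alone, mean -2.80, adjusted p = 1.38e-07; adjusted p = 0.732 with an estimated correlation), including Zfp57, which protects imprints (-2.42 ± 0.37), and Tet1 (-2.75 ± 0.55). Their level differed widely between lines. Pou5f1 intensity was 7410.3 in TKO EB Dutch, 6132.8 in 14-14-4, 1542.2 in 2-55-2, 146.8 in 7-4-1 and 17.1 in Ta1-12, against 32.8 to 55.2 in WT EB and 9879.8 to 12950.1 in ESC of both genotypes. Of 10 primitive ectoderm genes 6 fell (6 adjusted over the list alone, mean -1.74, adjusted p = 0.00644; adjusted p = 0.732 with an estimated correlation), among them Foxd3 (-2.70 ± 0.53) and the DNA methyltransferase Dnmt3b (-2.47 ± 0.81). The call of this list was lost without genes of chromosomes 1, 8, 11, 12 and 19 (-1.6, adjusted p = 0.0545). Of 14 germline genes 5 fell (5 adjusted over the list alone, mean -1.55, adjusted p = 0.00644; adjusted p = 0.746 with an estimated correlation), such as Ddx4 (-3.33 ± 0.90). Germline genes had -2.381 without TKO EB Dutch and 14-14-4.

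Few E2F targets and G2/M genes moved in TKO EB against TKO ESC, while most CDK inhibitors rose. Of 39 E2F targets 5 fell and 1 rose (2 and 0 adjusted over the list alone, mean -0.32, adjusted p = 0.042; adjusted p = 0.746 with an estimated correlation). Cyclin E1, Ccne1, which drives entry into S phase, fell (-1.75 ± 0.33), as did Orc1 (-2.06 ± 0.45), Mybl2 (-2.49 ± 0.73) and Msh6 (-1.09 ± 0.34). The call of E2F targets was lost without TKO ESC 7-4-1 (-0.285), without TKO EB Dutch (-0.387), without TKO EB Ta1-12 (-0.093) under quantile normalization (-0.415, adjusted p = 0.0832), without line Ta1-12 (-0.126, adjusted p = 0.364) and without genes of chromosomes 1, 8, 11, 12 and 19 (-0.389, adjusted p = 0.0661). Without TKO EB Dutch and 14-14-4 the mean was -0.482 and passed (adjusted p = 0.0215). None of 34 G2/M genes passed (0 adjusted over the list alone, mean -0.20, adjusted p = 0.188), with Bub1b at -0.79 ± 0.39 and Plk1, a mitotic kinase, at -0.66 ± 0.39. Of 7 CDK inhibitors 6 rose (7 adjusted over the list alone, mean 2.63, adjusted p = 1.85e-04; adjusted p = 0.241 with an estimated correlation), with Cdkn1c at 4.36 ± 0.57, Cdkn2c at 4.07 ± 0.54, Cdkn1a at 2.16 ± 0.22 and Cdkn1b at 2.12 ± 0.34. Ccnd2 rose by 3.61 ± 0.62 and Cdk4, the partner of D cyclins, by 0.36 ± 0.13, 2 of 6 in their list (1 adjusted over the list alone, mean 0.71, adjusted p = 0.385). E2f4 fell (-1.41 ± 0.17), while E2f6 and E2f1 rose by 1.02 ± 0.22 and 0.49 ± 0.17 (the same 2 rises and 1 fall of 10 adjusted over the list alone, mean -0.06, adjusted p = 0.551).

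Tissue lists rose in TKO EB as well. Of 16 fibroblast genes 14 rose (14 adjusted over the list alone, mean 4.61, adjusted p = 8.85e-11; adjusted p = 0.241 with an estimated correlation). Of 20 endoderm genes 15 rose (16 adjusted over the list alone, mean 3.27, adjusted p = 5.41e-06), of 10 parietal endoderm genes 7 (7 adjusted over the list alone, mean 2.21, adjusted p = 0.00134), of 6 smooth muscle genes 3 (3 adjusted over the list alone, mean 2.53, adjusted p = 0.0221) and of 26 cardiac genes 11 (11 adjusted over the list alone, mean 2.23, adjusted p = 0.0011). The adjusted p was 0.732 for the first 3 of these and 0.746 for cardiac genes with an estimated correlation. Smooth muscle genes lost their call without TKO EB Dutch (2.489, adjusted p = 0.058). Afp rose by 7.48 ± 0.63, Ttr by 7.20 ± 0.48, Acta2, smooth muscle actin, by 5.03 ± 0.62, Actc1, cardiac actin, by 6.61 ± 1.40 and Hand2 by 4.77 ± 0.44. Of 17 neural progenitor genes 6 rose and 1 fell (6 and 1 adjusted over the list alone, mean 1.16, adjusted p = 0.188), with Zic1 at 4.77 ± 0.77.

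In TKO EB versus TKO ESC 5132 genes (35.7%) passed, 2987 higher and 2145 lower, 3085 of them at least 2-fold. After quantile normalization 2616 genes were higher and 2769 lower, so the direction of the majority depended on the scaling. With the line as a block, on the 3 lines measured at both stages, 193 genes passed (179 higher, 14 lower), 31 of 112 named genes kept their call and 81 lost it. The kept ones included Ccne1, Cdkn1c, Hand2, Afp, Ttr, Acta2 and Actc1. Relative to the median of all genes (0.08 as deposited, -0.04 after quantile normalization), the mean changed by -0.40 for E2F targets, -0.29 for G2/M genes and -2.88 for pluripotency genes.

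The change on differentiation was compared directly between genotypes. E2F targets, G2/M genes, pluripotency genes and primitive ectoderm genes had a smaller decrease in TKO than in WT cells, by a mean of 0.89, 0.99, 1.54 and 1.82 on the log2 scale (camera adjusted p = 1.55e-20, 5.28e-17, 1.35e-05 and 1.35e-05). Germline genes differed in the same way (1.06, adjusted p = 7.25e-04), and cardiac (-1.18, adjusted p = 5.76e-04), parietal endoderm (-0.99, adjusted p = 0.0102) and the D cyclins and CDKs (-0.74, adjusted p = 0.0454) in the other. With an estimated correlation the adjusted p was 0.762 for each of these 8 lists. Exact permutation over the lines measured at both stages, which cannot go below p = 0.1, gave 0.3 for E2F targets, 0.3 for G2/M genes and 0.7 for pluripotency genes. It left out the TKO EB lines without an ESC array, so these p-values do not belong to the mean differences above. Without TKO EB Dutch and 14-14-4 the difference of pluripotency genes was 0.254 and its call was lost (adjusted p = 0.333). These arrays were picked for the highest pluripotency means among TKO EB (11.49 and 11.03), so a smaller difference follows by construction and says nothing about stability. Calls were also lost without them for cardiac (-0.37), parietal endoderm (-0.592), germline (0.227) and D cyclin and CDK genes (-0.648), and E2F targets, G2/M genes and primitive ectoderm genes (1.08) still passed. Without WT EB B21 the difference was 0.521 for E2F targets and 0.639 for G2/M genes, both still passing, and without TKO EB Dutch it was 0.997 for pluripotency and 0.421 for germline genes, also passing. Without TKO EB 14-14-4 cardiac genes had -0.785 and still passed. Germline genes lost their call without WT ESC B21 (0.676). Parietal endoderm genes lost it without WT EB R1 (-0.376), TKO EB Dutch (-0.707), TKO ESC 7-4-1 (-0.796) or WT ESC B21 (-0.817). The D cyclins and CDKs lost it without TKO EB 7-4-1 (-0.59), WT ESC B21 (-0.598), TKO EB Dutch (-0.608), TKO ESC Ta1-12 (-0.656), WT EB J1 (-0.72) or WT EB R1 (-0.784), without a filter (-0.741, adjusted p = 0.0594) and with the mean of probe sets (-0.71). The replication helicase subunits Mcm6, Mcm4 and Mcm3 had interaction terms of 0.82 ± 0.27, 0.80 ± 0.29 and 1.17 ± 0.44, Cdk1, the kinase of mitotic entry, 0.59 ± 0.28, Fgf5, a marker of primitive ectoderm, 3.71 ± 1.02, Pou3f1 2.12 ± 0.75, Sox2 0.94 ± 0.40, Ccnd2 -2.004 ± 0.93 and Ccnd3 -0.80 ± 0.24 (adjusted p = 0.975 for each of these genes).

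No single gene passed in the interaction (0 by limma, 522 at an unadjusted p under 0.05, against 718 by chance). Leaving out TKO EB Ta1-12 gave 26 genes. Members passing when adjusted over the list alone were 1 primitive ectoderm gene and 1 of the D cyclins and CDKs, and none of the E2F, G2/M or pluripotency lists. Fold changes on differentiation correlated across genes between WT and TKO at r = 0.915 and rho = 0.895 with a slope of 0.757, where genes are not independent replicates. Of the called genes, 2536 were higher in both genotypes (783 for independent lists) and 1658 lower in both (372), and 1 was called in opposite directions.

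In undifferentiated cells no single gene passed between the genotypes. The lists that passed by camera in TKO ESC against WT ESC (n = 3 and 3) were smooth muscle genes (-1.17, camera adjusted p = 0.00746), imprinted genes (-0.60, adjusted p = 0.0465) and pluripotency genes (0.32, adjusted p = 0.0467), each with adjusted p = 0.977 with an estimated correlation. Adjusted over the list alone, 0, 1 and 0 members passed. Smooth muscle genes averaged 7.35, 8.72 and 9.69 in WT ESC B21, J1 and R1 and 6.71 to 7.93 in TKO ESC. Other lists had negative means without passing, such as epithelial (-0.51, adjusted p = 0.248), fibroblast (-0.38, adjusted p = 0.0815) and primitive ectoderm genes (-0.36, adjusted p = 0.629). The epithelial mean was 9.87 and 10.19 in WT ESC J1 and R1 and 9.02 to 9.36 on the other ESC arrays, and the pluripotency mean was lowest in WT ESC R1 (11.39 against 11.87 to 12.21). Tagln and Myl9, of the smooth muscle cytoskeleton, had log2 fold changes of -2.28 ± 0.99 and -1.58 ± 0.55, the imprinted zinc finger gene Plagl1 -1.91 ± 0.40 (adjusted p = 0.958) and Fgf5 -2.63 ± 0.76. Cell cycle lists showed small values, with a mean of 0.10 for E2F targets (31 of 39 above 0; adjusted p = 0.0684), -0.02 for G2/M genes (15 of 34 above 0; adjusted p = 0.779) and 0.15 for the E2F family (adjusted p = 0.248). Thymidylate synthase, Tyms, had 0.72 ± 0.32 and E2f2 1.09 ± 0.71. The Notch receptor Notch3 had -1.01 ± 0.32, B2m, the light chain of MHC class I, -1.16 ± 0.35 and the stress response factor Jun -1.65 ± 0.62. Where no other value is given, the adjusted p of these genes was 1.

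No gene passed in TKO ESC versus WT ESC by limma (0 genes; 394 at an unadjusted p under 0.05, 96 higher and 298 lower, against 718 by chance). Leaving out WT ESC B21 gave 5 genes and leaving out TKO ESC Dutch gave 1, and with array weights 697 passed (153 higher, 544 lower). The pluripotency difference passed without WT ESC B21 (0.511) and lost its call without each of the others, at 0.10 (adjusted p = 0.516) without WT ESC R1, 0.341 without WT ESC J1, 0.354 without TKO ESC 7-4-1, 0.293 without TKO ESC Dutch and 0.305 without TKO ESC Ta1-12. Smooth muscle genes lost their call without WT ESC R1 (-0.615) or TKO ESC 7-4-1 (-0.811) and had -1.783 without WT ESC B21. Imprinted genes lost it without TKO ESC 7-4-1 (-0.299), WT ESC R1 (-0.404), WT ESC J1 (-0.473) or TKO ESC Dutch (-0.673), without a filter (-0.572), with the mean of probe sets (-0.405) and without genes of chromosomes 1, 8, 11, 12 and 19 (-0.367, adjusted p = 0.423), and had -0.924 without WT ESC B21. E2F targets passed without WT ESC J1 (0.132, adjusted p = 0.0483).

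In EB, cell cycle and pluripotency genes lay higher in the TKO group than in the WT group (n = 5 and 3), without any single gene passing. The mean of the 39 E2F targets was 11.49 ± 0.51 in TKO EB and 10.498 ± 0.66 in WT EB (SD, log2), a difference of 0.99 with 39 of 39 genes above 0 (camera adjusted p = 2.96e-31; adjusted p = 0.627 with an estimated correlation). By exact permutation of arrays p was 0.0714. Adjusted over the list alone 37 of them passed, and 0 over all genes. In ESC the same mean was 11.70 ± 0.06 in WT and 11.81 ± 0.07 in TKO. The 34 G2/M genes differed by 0.98 (34 above 0; adjusted p = 1.85e-21; adjusted p = 0.627 with an estimated correlation; exact permutation p = 0.125; 0 adjusted over the list alone). Without WT EB B21 both differences were 0.623, and both still passed by camera. With the pluripotency mean as a covariate they were 0.713 and 0.564, and by exact permutation the first of these had p = 0.196.

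The TKO arrays were not alike. E2F targets averaged 11.77 in TKO EB 7-4-1, 11.76 in Dutch, 11.70 in 14-14-4, 11.62 in 2-55-2 and 10.58 in the array labelled TKO Ta1-12, against 9.77, 11.03 and 10.69 in WT EB B21, J1 and R1. G2/M genes averaged 12.02, 11.95, 11.70, 11.72 and 10.10 in the same TKO lines and 9.81, 10.89 and 10.86 in WT. Cdk1 intensity was 11162.8, 10036.4, 9692.6, 10285.7 and 6069.8 in these TKO EB, and 4842.9, 7490.9 and 7471.1 in WT EB. The helicase subunits Mcm3, Mcm2, Mcm6 and Mcm4 had log2 fold changes of 1.20 ± 0.29, 0.74 ± 0.19, 0.72 ± 0.18 and 0.70 ± 0.19, the repressor E2Fs E2f8 and E2f7 1.30 ± 0.45 and 1.39 ± 0.53, and the mitotic genes Cenpf and Ndc80 1.54 ± 0.51 and 1.31 ± 0.43 (adjusted p = 0.303, and 0.317 for E2f7). The E2F family as a list had a mean of 0.38 (adjusted p = 0.0176; adjusted p = 0.668 with an estimated correlation; 0 adjusted over the list alone). That call was lost without TKO EB 7-4-1 (0.26) or WT EB R1 (0.27) and with only the 3 TKO lines measured at both stages (0.319), and the mean was 0.577 without WT EB J1. Ccnd2 and Ccnd3 had -2.002 ± 0.62 and -0.63 ± 0.16 (adjusted p = 0.303), 2 members of their list passing when adjusted over the list alone (list mean -0.66, adjusted p = 0.125). CDK inhibitors had a mean of 0.05 (adjusted p = 0.567; 0 adjusted over the list alone).

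**Figure D2:**
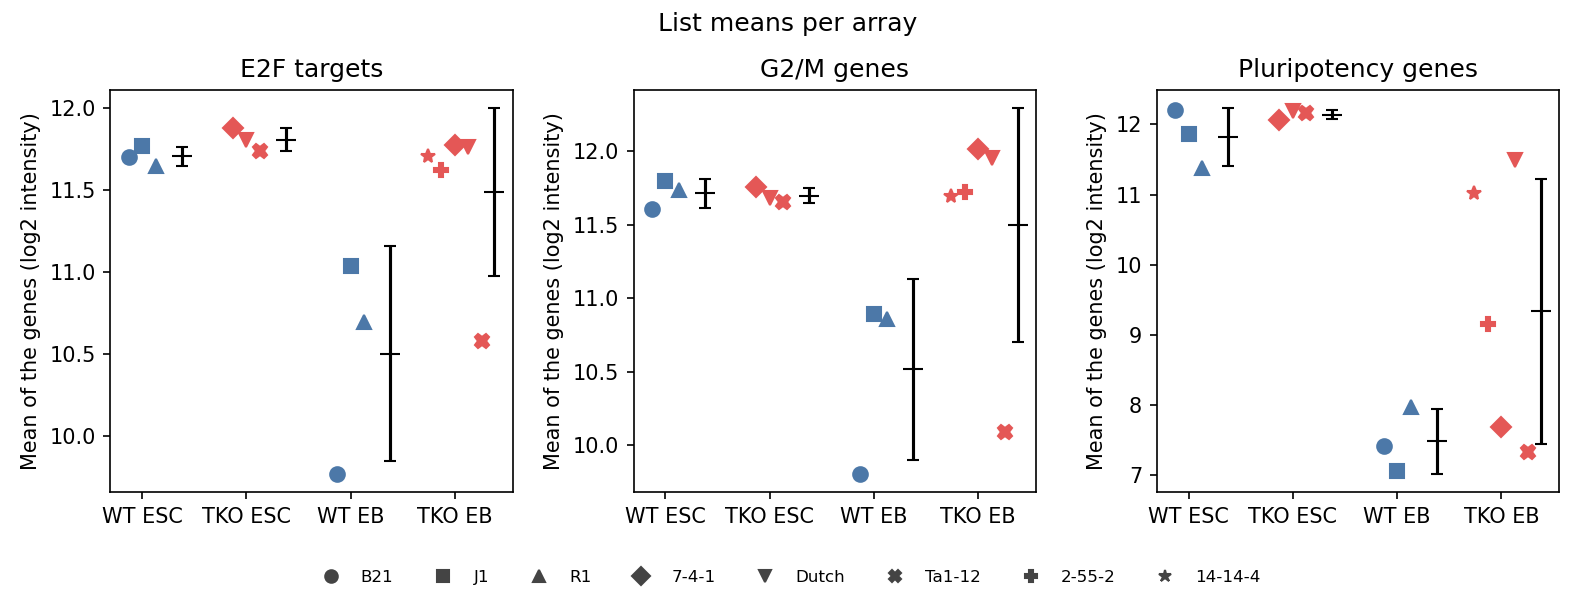
Mean log2 intensity of E2F targets, G2/M genes and pluripotency genes on each array, by group, with a marker shape per line and, at the right of each group, the group mean with its SD. In EB the E2F mean is 11.62 to 11.77 in 4 TKO lines, 10.58 in TKO Ta1-12 and 9.77 to 11.03 in WT lines.

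Pluripotency genes were higher by a mean of 1.85 in TKO EB (25 of 27 above 0; camera adjusted p = 1.56e-11; adjusted p = 0.646 with an estimated correlation; exact permutation p = 0.214; 1 adjusted over the list alone), with Pou5f1 at 4.28 ± 1.42, Nanog at 3.94 ± 1.35, Utf1 at 3.35 ± 1.24 and Sox2 at 1.06 ± 0.27 (adjusted p = 0.303, and 0.312 for Utf1). The array means were 11.49 in Dutch, 11.03 in 14-14-4, 9.16 in 2-55-2, 7.69 in 7-4-1 and 7.33 in Ta1-12, and 7.06 to 7.98 in WT EB. Primitive ectoderm genes had a mean of 1.46 (10 of 10 above 0; adjusted p = 1.03e-05; adjusted p = 0.627 with an estimated correlation; 0 adjusted over the list alone), with the Nodal pathway genes Lefty2 at 3.36 ± 1.18 and Nodal at 2.65 ± 1.04 (adjusted p = 0.303 and 0.317). Germline genes had 0.88 (adjusted p = 7.01e-04; adjusted p = 0.668 with an estimated correlation; 0 adjusted over the list alone), with the meiotic cohesin subunit Stag3 at 1.88 ± 0.89 (adjusted p = 0.36). Without TKO EB Dutch and 14-14-4, picked for their pluripotency means, the means were 0.572 for pluripotency, where a smaller value follows by construction, 0.718 for primitive ectoderm and 0.051 for germline genes, and the last lost its call (adjusted p = 0.315). Without TKO EB Dutch alone germline genes had 0.245 and passed (adjusted p = 0.0471). With only the 3 TKO lines measured at both stages primitive ectoderm genes had 0.882 and passed. With the pluripotency mean as a covariate they lost their call (0.304, adjusted p = 0.0528).

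The group means of 4 tissue lists were lower in TKO EB than in WT EB by camera. Cardiac genes had a mean of -1.33 (25 of 26 below 0; adjusted p = 1.62e-04; 0 adjusted over the list alone), parietal endoderm genes -1.02 (10 of 10; adjusted p = 0.00736; 1 adjusted over the list alone), fibroblast genes -0.86 (15 of 16; adjusted p = 0.0117; 4 adjusted over the list alone) and epithelial genes -1.13 (10 of 10; adjusted p = 0.0153; 0 adjusted over the list alone). With an estimated correlation the adjusted p was 0.668 for each. Myocd, a coactivator of muscle genes, had -1.04 ± 0.39, the endothelial and endodermal receptor Thbd -2.37 ± 0.67, the matrix genes Ogn and Lox -2.52 ± 0.71 and -2.17 ± 0.69, S100a4 -2.64 ± 0.80 and the basal keratins Krt5 and Krt14 -3.16 ± 1.22 and -1.91 ± 0.67 (adjusted p from 0.303 to 0.317). The cardiac mean was 6.62 in TKO EB 14-14-4, 7.35 in Dutch, 8.04 in 7-4-1, 8.75 in Ta1-12 and 10.24 in 2-55-2, and 8.74 to 9.998 in WT EB. The epithelial mean was 8.55 in TKO EB 7-4-1, 10.07 in 14-14-4, 10.27 in Dutch, 10.92 in 2-55-2 and 11.93 in Ta1-12, and 11.39 to 11.60 in WT EB. Without TKO EB Dutch and 14-14-4, arrays picked for the highest pluripotency means and lowest also in cardiac genes, cardiac (-0.522, adjusted p = 0.138), parietal endoderm (-0.627, adjusted p = 0.108) and fibroblast genes (-0.387, adjusted p = 0.259) lost their call and epithelial genes passed (-1.012, adjusted p = 0.0159). With the pluripotency mean as a covariate the same 3 lost it (-0.542, -0.526 and -0.21) and epithelial genes passed (-1.007, adjusted p = 0.00655). Leaving out 1 array ended the call of epithelial genes (-0.679 without TKO EB 7-4-1), parietal endoderm genes (-0.412 without WT EB R1) and fibroblast genes (-0.736 without WT EB J1). Epithelial genes also lost it without genes of chromosomes 1, 8, 11, 12 and 19 (-1.123, adjusted p = 0.119). Neural progenitor genes (mean 0.00, adjusted p = 0.294) and postmitotic neuron genes (0.08, adjusted p = 0.106) showed no such shift by camera, but the lines differed widely. The postmitotic neuron mean was 9.42 in TKO EB 7-4-1, 7.75 in 2-55-2, 7.23 in Dutch, 6.64 in 14-14-4 and 6.36 in Ta1-12, and 6.70 to 8.47 in WT EB. The neural progenitor mean ran from 7.26 to 9.46 in TKO EB and from 7.81 to 8.66 in WT EB.

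By limma 0 genes passed in TKO EB versus WT EB, with 2034 at an unadjusted p under 0.05 (643 higher, 1391 lower; 718 by chance). The median of all genes was -0.10 as deposited and 0.00 after quantile normalization, and relative to it E2F targets were higher by 1.09 and 1.09, G2/M genes by 1.08 and 1.09, and pluripotency genes by 1.95 and 1.94, while cardiac genes had -1.23 and -1.23. Leaving out TKO EB Ta1-12 gave 1422 genes (480 higher, 942 lower) in the fit over all arrays but 23 in a fit of the 7 remaining EB arrays alone. Leaving out WT EB R1 gave 2 and 0, and leaving out any of the other 6 EB arrays gave 0 in both. The median SD of a gene was 0.211 and 0.194 in WT and TKO ESC and 0.281 and 0.416 in WT and TKO EB, so the fit over all arrays rests on a spread that is smaller than that among TKO EB. The genotype effects in ESC and EB correlated across genes at r = 0.251 (rho = 0.265), with the lines B21, J1, R1, 7-4-1, Dutch and Ta1-12 in both.

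Shifts of expression along whole autosomes were seen on arrays of both genotypes. The median shift on chromosome 1 was 0.29 in EB and 0.27 in ESC of TKO 7-4-1, against the median of all arrays of the same stage. In line B21 it differed between stages, at 0.254 in ESC and 0.008 in EB on chromosome 1 and -0.008 and 0.352 on chromosome 19.

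**Figure D3:**
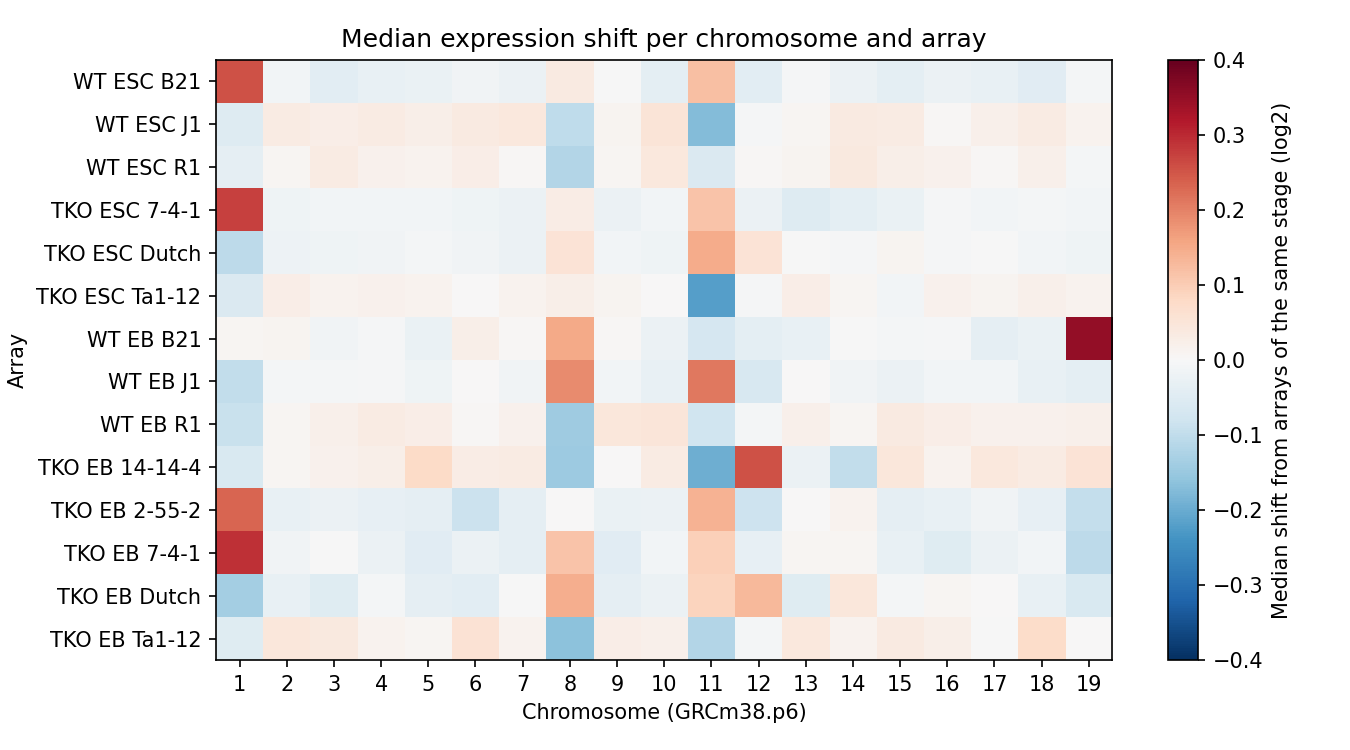
Median shift of log2 intensity per autosome and array from the median of all arrays of the same stage. The largest is 0.35, on chromosome 19 of WT EB B21.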

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

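All tests of explanations below were chosen after the result was seen, except the regroupings of the ESC and EB arrays within a genotype. In 35 measures of the 5 TKO EB arrays, 6 had 1 array far from the others by Dixon's criterion, where chance gives about 1 in 20 groups. The array labelled TKO Ta1-12 stood apart in the list means of E2F targets (10.58, with the other 4 at 11.62 to 11.77), G2/M genes (10.10, others 11.70 to 12.02), endothelium (9.27, others 6.80 to 7.44) and endoderm (11.47, others 9.10 to 9.23). TKO EB Dutch stood apart in CDK inhibitors (10.19, others 10.96 to 11.27) and germline genes (9.12, others 5.59 to 6.51).

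The change on differentiation differed between TKO and WT cells by camera for 8 lists. The differences were 0.886 for E2F targets, 0.994 for G2/M genes, 1.535 for pluripotency, 1.822 for primitive ectoderm, 1.057 for germline genes, -0.741 for D cyclins and CDKs, -1.18 for cardiac muscle and -0.985 for parietal endoderm. None held with an estimated correlation between genes, where the adjusted p was 0.762.

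By camera the group means of cell cycle genes were higher in TKO EB than in WT EB, by 0.988 for E2F targets and 0.978 for G2/M genes. Both calls were lost with an estimated correlation (adjusted p = 0.627), neither list passed by exact permutation (p = 0.0714 and 0.125), and Ta1-12 did not share the difference (10.58 and 10.10). The 29 E2F targets outside chromosomes 1, 8, 11, 12 and 19 differed by 1.00 (SE over genes 0.077, which is not a spread between lines). This argues against the gene dosage of these chromosomes as the source of the difference. An indirect effect of gained or lost chromosomes on genes elsewhere could not be seen this way and stayed open. For residual undifferentiated cells, an ESC-like share placed each EB array between the mean of WT EB and the mean of ESC. It was the median over the genes of a list that were higher in ESC than in WT EB on these same arrays. The share computed from E2F targets was set against that from pluripotency genes. The gap was 89.6 percent points in 7-4-1 (90.5% against 0.9%) and 60.1 in 2-55-2 (67.2% against 7.2%). In WT EB, whose mean is the zero point of both shares, it ran from -25.6 to 25.1, around that point by construction. These values argue against residual cells as the source of the E2F levels in 7-4-1 and 2-55-2. For E2F targets in Dutch (91.8% against 74.6%) and 14-14-4 (70.3% against 49%) this explanation stayed open, and Ta1-12 showed no rise (-3.2% against -0.3%). Computed from G2/M genes, the share was 130.9% in Dutch, 80.9% in 14-14-4, 107.6% in 7-4-1, 77.8% in 2-55-2 and -20% in Ta1-12. It was -27.5% to 12.3% in WT EB. In Dutch and 14-14-4 the G2/M share thus lay further above the pluripotency share than the E2F share did. How much residual cells gave to it was not tested. For the group difference of E2F targets, residual cells also stayed open as an explanation. The gap was larger by 35.7 percent points in TKO EB than in WT EB (exact permutation p = 0.214). With the pluripotency mean as a covariate the difference of E2F targets was 0.713 against 0.988 without it (exact permutation p = 0.196). The poly-A spike signals of 2-55-2 and 14-14-4 were 423 and 549, against 909 to 1386 elsewhere. Separate labelling of these lines was weighed as a possibility from these signals and is not stated in the sample titles. It would not account for the levels of 7-4-1 (11.77) and Dutch (11.76), which lay above those of both. Without 2-55-2 and 14-14-4 the difference was 0.872 against 0.988 with them. The share of such a labelling in the group difference stayed open, because the SE between arrays of the 0.872 was 0.547 and Ta1-12 (10.58) lay under WT EB J1 (11.03). Loss of the Rb family, which the design names, remains among the open explanations and was not tested apart from these.

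The array labelled TKO Ta1-12 EB had WT levels of cell cycle genes. A swap of TKO EB and WT EB arrays was weighed by E2F targets, where the highest WT EB mean was 11.034 and the lowest of the other TKO EB was 11.62. This argues only against a swap with an array at the E2F level of the other TKO EB. A swapped TKO culture with WT levels of E2F targets would not be seen. A wrong label without a partner in these groups is not excluded by that. A candidate explanation is that Ta1-12 does not carry the same Rb family alleles as the other TKO lines. Its mean Rbl1 intensity was 794.2, with WT arrays at 356 to 1090. In 7-4-1 and the TKO lines measured only as EB the same probe set lay at 15.9 to 38.3. A second Rbl1 probe set lay at 12.7 to 36.6 there, but at 328.2 and 194.2 in ESC and EB of Ta1-12. These values argue against Ta1-12 sharing the Rbl1 allele of those lines. Dutch was at 250.3 and 377.1, and for Rb1 and Rbl2 the probes may lie outside the deleted part. Whether Ta1-12 differs from Dutch, and whether its alleles account for its cell cycle levels, stayed undecided. More complete differentiation of this culture also stayed undecided, with a pluripotency mean of 7.333, because only 7-4-1 had a similarly low mean (7.69) and its E2F targets were at 11.77.

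Regrouping the arrays gave the following, in fits of the compared groups alone. For WT EB versus WT ESC the real grouping gave 6641 genes and the highest of the others 0, as 1 of 10 splits, and 10 splits are too few for a share under 0.05. For TKO EB versus TKO ESC the real grouping gave 3873 genes, the most of 56 splits (1 of 56), which argues against chance. The highest other gave 2165 and put TKO EB Dutch and 14-14-4 with the ESC arrays, which points to a structure of the samples. For TKO EB versus WT EB the real count was 0, which each of 56 splits reaches by construction, so this count says nothing about chance. The highest other gave 319 genes and set WT EB J1 with the TKO lines 2-55-2, 14-14-4, 7-4-1 and Dutch, which also points to a structure of the samples. For TKO ESC versus WT ESC the real count was 0 and the highest other 10, which set WT ESC B21 with TKO ESC 7-4-1 and Dutch. For the interaction these counts were 0 and 0. In both comparisons 10 splits are too few for a share under 0.05, and all 10 reach a count of 0 by construction.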

How the results depend on the processing

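The fits without line Ta1-12, without TKO EB Dutch and 14-14-4, with the pluripotency covariate, without genes of chromosomes 1, 8, 11, 12 and 19 and the permutations were chosen after the data were seen. Ta1-12 was picked for its measured Rbl1 and EB cell cycle genes and Dutch and 14-14-4 for their pluripotency genes, so values without them compare arrays selected by an outcome and say nothing about stability. Quantile normalization, a floor of 16, an added constant of 16 without floor, a prior without trend, a random block for the line, mean or non-cross-hybridising probe sets, a stricter filter and only the TKO lines with both stages changed no gene count by over 1.5 times. The cause of the changes below was not tested, except where fewer or more features were counted.

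In TKO ESC versus WT ESC 2 genes passed without a filter, 697 with array weights and 1 with a floor of 64. In TKO EB versus WT EB 8 passed with array weights, 10 with a floor of 64 and 1101 without line Ta1-12. In the interaction 1 passed without a filter, 4 with array weights and 5 without line Ta1-12. Testing every probe set by itself gave 11186 in WT EB versus WT ESC and 9460 in TKO EB versus TKO ESC. The latter comparison gave 3085 genes with a 2-fold minimum, 193 with the line as a replicate block (on 6 arrays) and 3068 without line Ta1-12. In the block fit p53 targets lost their call there (0.562, adjusted p = 0.176, against 0.65 and 0.042 in the main fit). No other list call or gene count changed. The p53 call was already lost without a block on only the 3 TKO lines measured at both stages (0.562, adjusted p = 0.121). Its loss can thus not be put down to the block alone. Of named genes called, 5 of 124 in WT and 81 of 112 in TKO lost their call in the block fit. In TKO that fit, on 6 arrays, also left out the EB lines without an ESC array. The losses of named genes in TKO can thus not be put down to the block alone either.

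Leaving out 1 array at a time gave 0 to 5 genes in TKO ESC versus WT ESC (5 without WT ESC B21, 1 without TKO ESC Dutch), 0 to 1422 in TKO EB versus WT EB (1422 without TKO EB Ta1-12, 2 without WT EB R1), 4589 to 5613 in WT EB versus WT ESC, 3559 to 6233 in TKO EB versus TKO ESC and 0 to 26 in the interaction (26 without TKO EB Ta1-12, 1 without WT EB R1). The correlation of genotype effects ran from 0.174 to 0.267 and that of differentiation effects from 0.863 to 0.926. List means in ESC ran from 0.067 to 0.136 for E2F targets, -0.07 to 0.027 for G2/M genes and 0.1 to 0.511 for pluripotency, whose call was lost in 5 of 6 cases. In EB they ran from 0.623 to 1.256, 0.623 to 1.329 and 1.314 to 2.354, and in the interaction from 0.521 to 1.154, 0.639 to 1.345 and 0.997 to 2.037, with no call lost.

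The pluripotency difference in ESC (0.317) lost its call under quantile normalization (0.319), without a filter (0.317), with mean probe sets (0.32), without line Ta1-12 (0.305) and without the shifted chromosomes (0.303), at adjusted p from 0.0669 to 0.154. E2F targets in ESC passed without line Ta1-12 (0.136, adjusted p = 0.0121) and without WT ESC J1 (0.132, adjusted p = 0.0483). With an estimated correlation the call was lost for pluripotency in ESC, for E2F targets, G2/M genes and pluripotency in EB (0.988, 0.978 and 1.852) and in the interaction (0.886, 0.994 and 1.535). By exact permutation of arrays, also against no change, the 3 lists in EB did not pass. In ESC and the interaction exact permutation cannot go below p = 0.1, so a missed threshold there says nothing about stability. The p obtained by it was 0.4 for pluripotency in ESC. In the interaction it was 0.3 for E2F targets, 0.3 for G2/M genes and 0.7 for pluripotency. In ESC and EB the means are the same by construction. In the interaction the permutation used only the lines measured at both stages. It left out the TKO EB lines without an ESC array, so its p does not belong to the means of 0.886, 0.994 and 1.535. By fry, which tests a list against no change and not against other genes, none of the list calls named in this paragraph held (smallest adjusted p 0.243). Over all list results followed, including lists that had not passed, fry by direction left 25 the same and 24 weaker. Its mixed form, which ignores direction, left 27 the same and 22 weaker. Exact permutation left 10 the same and 39 weaker, where comparisons of 3 arrays against 3 cannot pass. Pluripotency in the interaction fell to 0.254 without TKO EB Dutch and 14-14-4 and lost its call (adjusted p = 0.333), and in EB it fell to 0 with its own mean as a covariate, both by construction. Under that covariate germline genes reversed (-0.209). Hoxa5 reversed in WT EB versus WT ESC with mean probe sets (0.789) and without cross-hybridising types (3.035), and Dnmt3a in TKO EB versus TKO ESC with mean probe sets (0.58). Signal under the floor of 32, 25.7% to 29% of probe sets per array, limits fold changes of dim genes.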

Other observations

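The test of chromosome profiles below was chosen after the result was seen. Several gene groups outside the cell cycle and tissue lists moved on differentiation. Of 20 imprinted genes 12 rose and 1 fell in WT EB against WT ESC (12 and 1 adjusted over the list alone, mean 1.65, camera adjusted p = 0.00426; adjusted p = 0.536 with an estimated correlation) and 11 rose and 1 fell in TKO EB against TKO ESC (12 and 1 adjusted over the list alone, mean 1.67, adjusted p = 0.0013; adjusted p = 0.557 with an estimated correlation). Dlk1 rose by 7.09 ± 0.40 in WT and Plagl1 by 3.14 ± 0.40 in WT and 4.87 ± 0.35 in TKO, and the growth factor Igf2 rose by 6.30 ± 0.67 in TKO. The noncoding imprinted transcripts Meg3 and Rian had -5.23 ± 1.73 and -3.85 ± 1.06 in TKO EB against WT EB (adjusted p = 0.303). Immediate early genes rose in 8 of 11 cases in WT (9 adjusted over the list alone, mean 1.60, adjusted p = 0.0226; adjusted p = 0.551 with an estimated correlation) and in 6 in TKO, with 1 fall (8 and 1 adjusted over the list alone, mean 1.51, adjusted p = 0.0367; adjusted p = 0.746 with an estimated correlation), with Jun at 3.72 ± 0.62 and 4.55 ± 0.56 and Fos at 3.82 ± 0.67 and 3.64 ± 0.60. The immediate early call in TKO was lost without TKO EB Ta1-12 (1.286), TKO ESC Dutch (1.436) or TKO EB 14-14-4 (1.457), without the last and TKO EB Dutch (1.622) and with only the 3 TKO lines measured at both stages (1.408). Without genes of chromosomes 1, 8, 11, 12 and 19 it was lost in WT (1.324, adjusted p = 0.148) and TKO (1.252, adjusted p = 0.165). Of 19 p53 targets 8 rose and 1 fell in each genotype (8 and 1 adjusted over the list alone), with a mean of 0.47 in WT (adjusted p = 0.252) and 0.65 in TKO (adjusted p = 0.042; adjusted p = 0.746 with an estimated correlation; 0.562 and 0.176 with the line as a block). The call in TKO was also lost without TKO ESC Dutch (0.55), TKO EB 14-14-4 (0.573), TKO EB Ta1-12 (0.58) or TKO EB Dutch (0.64), without 14-14-4 and Dutch together (0.533), without line Ta1-12 (0.608), with only the 3 TKO lines measured at both stages (0.562) and without genes of the 5 chromosomes (0.38, adjusted p = 0.468). These targets include the death receptor Fas at 2.85 ± 0.47 and 3.50 ± 0.42. Apoptosis genes divided, with 7 of 16 rising and 1 falling in WT and 8 and 2 in TKO (adjusted p = 0.41 and 0.299), and Casp8 rose by 2.50 ± 0.43 and 2.60 ± 0.38.

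Hox genes, which pattern the body axis, rose in 6 of 17 cases in WT EB (1 fell; mean 1.61, adjusted p = 0.164) and in 8 in TKO EB (10 adjusted over the list alone, mean 1.82, adjusted p = 0.00644; adjusted p = 0.746 with an estimated correlation), with Hoxb2 at 4.79 ± 0.85 and 4.42 ± 0.76. The call in TKO was lost without genes of chromosomes 1, 8, 11, 12 and 19 (1.568, adjusted p = 0.0545). Hoxa5 fell by 1.46 ± 0.35 in WT EB, a direction that reversed with other probe sets (0.789 and 3.035). The other lists did not pass by camera on differentiation of WT or TKO cells, apart from smooth muscle in TKO. Their means were 2.17 for smooth muscle in WT (3 of 6 rose), 2.82 and 1.78 for skeletal muscle in WT and TKO, 0.55 and 0.73 for the Notch pathway, 0.88 and 0.61 for hypoxia and glycolysis, 1.08 and 0.68 for endothelium, 0.81 and 0.63 for blood, 0.67 and 0.78 for early mesoderm, 0.47 and 0.85 for trophoblast, 0.60 and 0.22 for glia, -0.22 and -0.01 for postmitotic neurons, 1.78 and 1.16 for epithelium, and 0.26 and 0.27 for reference genes. Of the reference genes, B2m rose by 2.31 ± 0.35 in WT and 2.84 ± 0.32 in TKO and Tbp fell by 0.60 ± 0.19 and 0.59 ± 0.17, so these are not flat across stages.

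The Y-linked gene Eif2s3y had an intensity of 8.2 and 18.7 in ESC and EB of line 7-4-1, 3 in TKO EB 2-55-2 and 4.9 in 14-14-4, against 597.5 to 3234.7 on the other arrays. Uty was at 8.3 to 18.3 on the same 4 arrays and at 102.2 to 435.3 elsewhere. The Xist probe set fell by 2.34 ± 0.46 in WT and 2.34 ± 0.41 in TKO on differentiation.

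Expression shifted along whole chromosomes, for 9352 genes with intensity above 200 and set against the median of all arrays of the same stage (chromosomes of assembly GRCm38.p6). The median shift on chromosome 1 was 0.29 in TKO EB 7-4-1, 0.27 in TKO ESC 7-4-1, 0.25 in WT ESC B21 and 0.23 in TKO EB 2-55-2, and it was 0.35 on chromosome 19 in WT EB B21 and 0.26 on chromosome 12 in TKO EB 14-14-4. The shifts of B21 were not shared by its other array (0.008 on chromosome 1 in EB and -0.008 on chromosome 19 in ESC). On chromosome 8 EB arrays ran from -0.165 (TKO Ta1-12) to 0.189 (WT J1), with 7 of 8 beyond 0.1 in either direction, and on chromosome 11 arrays ran from -0.221 (TKO ESC Ta1-12) to 0.212 (WT EB J1). A hypothesis is that such shifts may reflect a copy number carried by the line. Profiles over autosomes correlated between ESC and EB of the same TKO line at a mean of 0.739 and between different TKO lines at -0.339. Shifts from a shared median tend to set different lines against each other, so that negative value may be partly built in. The WT means were 0.058 and -0.126. The profile of WT ESC J1 matched WT EB R1 (0.837) and not WT EB J1 (-0.758), while WT R1 matched at 0.907 and B21 at 0.024. A wrong line label among these WT arrays is not excluded, and with one the WT pairs of the block fit would not hold. Over both genotypes a one-sided exact permutation of the 36 pairings gave p = 0.0833, so the hypothesis stayed undecided, and no DNA measurement was used here.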
